A study of Drosophila melanogaster with 2 samples.

How the data were processed

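Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on whole Drosophila melanogaster pupae at 2 days of age that carried a transgene for CG32121 fused to enhanced green fluorescent protein, and an antibody against the fluorescent protein was used, per the labels. Chromatin was fragmented by sonication, per the labels. The samples given form 1 group of 2 biological replicates, numbered in the labels and recorded there as separate biological samples. No untagged or input sample was analysed here, so no comparison between groups was made.

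The values analysed were the authors' peak lists in the dm6 assembly, whose arm lengths equalled those of the reference genome used here. There were 8 lists: for each replicate a list ranked by irreproducible discovery rate (IDR) and a thresholded one, and for the series 2 ranked and 2 thresholded lists made from both libraries together. The peak signal is the value deposited by the authors for each peak; its scale is not given in the sources used here, and it was used only to describe and rank peaks. The deposited −log10 values were the q value and the global IDR of a peak. Every peak of the thresholded lists had a global IDR of 0.01 or below. Per the notes deposited with the samples, a further input of undescribed content went into the thresholded lists. Aligner, peak caller and versions are not given in the sources used here. The number of reads behind each list is unknown, so no interval that needs sequencing depth is given, and intervals on shares of peaks or genes cover counting error only.

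The conservative thresholded list of the series was the main peak set. The ranked list with a signal for each replicate held 175 peaks within the same IDR limit that were not among the peaks of the conservative list; they were not analysed here, and genes beside them can therefore read as having no peak. The ranked lists were otherwise used for replicate signals and for candidate peaks above the IDR limit, meaning those that missed the threshold. A replicate's signal at a peak is that of the nearest summit within 200 bp in its own ranked list, except in the correlations. The correlations used the signals for each replicate held by the series' ranked list, which does not name the replicate of each value.

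Shared peaks overlapped by at least 1 bp, and the share was compared with 100 circular shifts of replicate 1's peaks along each arm. Replicate correlations are across peaks, which are not independent replicates. Each summit received the first class that applied in the order promoter (within 500 bp of a protein-coding transcription start site, TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, from Ensembl release 115. The promoter share was compared with 1000 sets of random positions on the same arms. A gene was called bound when a summit lay within 500 bp of any of its TSSs. The 22 gene lists, 2 of them defined by name patterns, and the 22 motifs were fixed in advance; 8 symbols were updated through recorded synonyms. Lists were tested with Fisher's exact test against all other protein-coding genes on 2L, 2R, 3L, 3R, 4 and X. Motifs were counted on either strand within 50 bp of summits and in 1 window of the same length centred 500 bp to a randomly drawn side, with an exact binomial test on discordant peaks. Peaks per arm were compared with the share of assembled length by an exact binomial test. Tests were two-sided except that of the replicate overlap, which was one-sided, and the Benjamini-Hochberg adjustment was applied within each family at 0.05.

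Genes named were CG32121, the gene with a TSS within 1 kb of each of the 25 strongest summits, up to 4 bound genes of highest signal and up to 2 unbound genes per list, and the 5 genes with the most separate peaks in the body or 1 kb upstream. Not every gene the rule allows is named. Neighbouring genes can share a peak.

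In simulations of the gene lists, genes were bound independently of each other. The list of 92 cytoplasmic ribosomal protein genes, planted above its real bound share of 45.7%, was called in 50 of 50 draws over 13945 genes. Lists left at random were called in 5 of 1050 cases. Neither count carries over to shorter lists, smaller excesses or genes that share peaks. A planted motif was called among 7000 simulated peaks, with 1 of 21 other motifs called, and 3 of 3 planted 6-mers were called with 2 of 2077 others. It was the motif 1 core, set into a larger share of peaks than the 0.547% of real summits that held it. For the arms, 0 of 6 were called with uniform positions, and an arm thinned on purpose was called. That arm was thinned far below the real ratio of 0.933 at 3R. The call therefore does not carry over to shifts as small as those of 3R, 3L (1.10) and X (1.07).

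Alternatives fixed before the data were examined were the other thresholded list of the series, each replicate's own list, a limit of 0.01 on the global IDR, promoter windows of 250 and 1000 bp, candidate peaks as background, lists matched on the number of TSSs (10000 draws), stricter overlaps, other sets of peaks for the correlation and motif tests, motif windows of 100 bp, and arms by their share of TSSs. A limit of 0.001, overlapping peaks collapsed to their strongest summit, flank windows matched on GC content, and lists matched on head-to-head arrangement besides TSS number were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.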

Results

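Binding of the CG32121-eGFP fusion protein was mapped by ChIP-seq in whole pupae of 2 days in 2 biological replicates. The conservative list held 7676 peaks with a median width of 396 bp and a median signal of 121.5, which merged into 7091 separate regions covering 2657116 bp. Replicate 1's own list held 4471 peaks and replicate 2's own list held 7044. The authors' signal per peak is used here to rank peaks. The number of sequenced reads is unknown.

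The first question was how well the replicates matched. Of the replicate 1 peaks, 3951 (88.4%, Wilson 95% interval 87.4 to 89.3) overlapped a replicate 2 peak, against a mean of 3.28% after circular shifts (permutation p = 0.0099, one-sided and the smallest that 100 shifts can give). In the other direction 3922 replicate 2 peaks (55.7%) overlapped a replicate 1 peak. Across the 7676 peaks the replicate signals held by the series' ranked list had a Spearman rho of 0.77 and a Pearson r of 0.88 on log values. These peaks had passed a limit on IDR, which asks for agreement between the replicates, so the selection itself favours a high correlation. At the 7322 peaks matched in both replicates the signal was higher in replicate 2 at 96.1%, with a median ratio of 1.72 (quartiles 1.41 and 2.07). Over all 91465 ranked peaks of the series rho was 0.46 and r was 0.55.

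**Figure D1:**
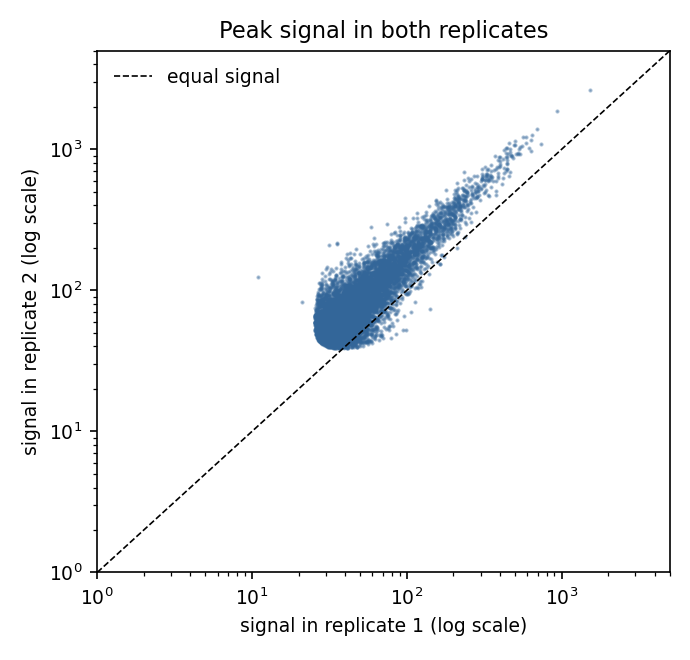
Signal of each main peak in replicate 1 (x axis) and replicate 2 (y axis), both as the authors' peak signal on log scales, 1 point per peak matched in both. Most points lie above the dashed line of equal signal, and the median ratio was 1.72.

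The strongest peak lay on 2L at 6612339 to 6613046 (dm6), inside CG11050 in an intron, with a signal of 4291 (1532 in replicate 1 and 2652 in replicate 2). It was followed by the promoters of Ugalt, a UDP-galactose transporter gene, with a summit 29 bp upstream of the TSS on X at 2703881 and a signal of 2789, and of CG14100, with a summit on 3L at 19590611 and a signal of 2061. PNPase, which encodes a mitochondrial RNA-degrading enzyme, had a signal of 1903. The homeobox gene Dll, which patterns the distal limb, had a promoter peak on 2R at 24814463 to 24814935 with a signal of 1829 (737 and 1084 in replicates 1 and 2). Promoter summits of CG18549 (1799), Tcs5 (1744), Syp (1680), CenG1A (1665), CG5611 (1593), CG7601 (1555), Fkbp14 (1549) and Lpin (1482) were also among the 25 strongest. The list included promoters of the mitochondrial ribosomal protein genes mRpL41 (1607) and mRpS10 (1436), of ph-p, a Polycomb group gene (1563), and of Chro, which encodes a chromodomain protein of interbands (1472). Intronic peaks in CG4496 (1493), CG32772 (1561), CG32486 (1558) and Trl, the GAGA factor gene (1453), and a peak inside osa (1607), belonged to the same set.

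The tagged gene itself, CG32121 (FBgn0052121, 3L at 13416576 to 13422336, minus strand), had 1 peak, at 13421087 to 13421192, in an intron and 1231 bp downstream of its TSS. Its signal of 237.2 ranked it 1332 among the peaks. The replicate signals there were 122.8 and 105.7, and the gene had no summit within 500 bp of its TSS. The animals carried a transgene for CG32121, and signal from it cannot be told apart here from signal at the gene's own locus.

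The next question was where in the genome the peaks lay. Summits fell in promoters for 2896 peaks (37.7%, Wilson 95% interval 36.7 to 38.8), against a mean of 11.4% for random positions (permutation p = 0.002, the smallest that 1000 sets can give). Introns held 3416 summits (44.5%, with 39.8% of the bases), intergenic sequence 1001 (13.04%, with 28.0% of the bases) and coding exons 60 (0.782%, with 13.2% of the bases). In 3' UTRs there were 77 summits (1.00%, with 5.15% of the bases), and 5' UTRs held 75. Promoter summits lay upstream of the nearest TSS in 1982 cases (68.4%, Wilson 95% interval 66.7 to 70.1, exact binomial p = 1.56e-89), with a median position of -86 bp and the highest count, 434, between -150 and -100 bp. Of 83242 candidate peaks that missed the threshold, 16.5% had a promoter summit, and the odds ratio of thresholded peaks over these was 3.06. The median signal was 122.7 for promoter, 121.4 for intronic and 123.0 for intergenic peaks.

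**Figure D2:**
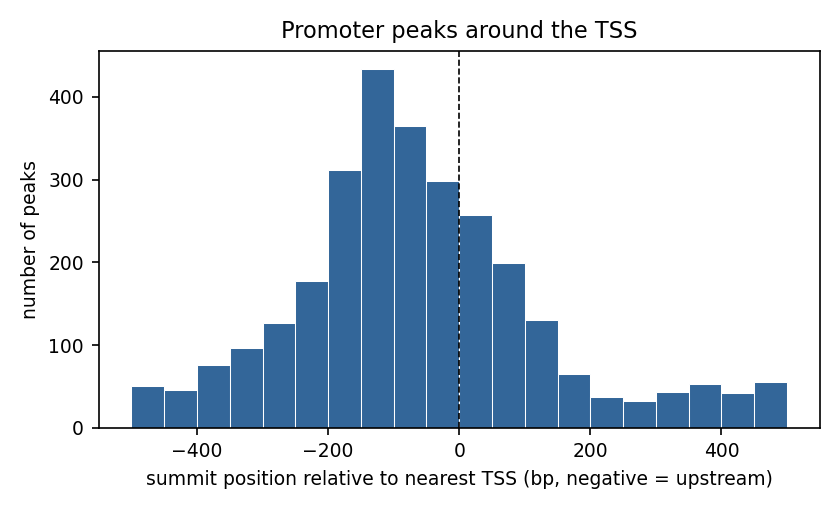
Number of promoter peaks (y axis) by summit position relative to the nearest protein-coding TSS in bp (x axis, negative is upstream), in bins of 50 bp. The 2896 summits peak upstream of the TSS, where 434 lie between -150 and -100 bp.

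Genes with many separate peak regions in the body or 1 kb upstream were led by Eip75B, an ecdysone-induced nuclear receptor gene, and sbb, each with 28 regions. Eip75B spans 113744 bp on 3L from 17950953 to 18064696, and sbb spans 79099 bp on 2R. They were followed by kirre, a myoblast fusion gene of 394149 bp (27 regions), Snoo (23), and, with 22 each, Eip74EF, an ecdysone-induced ETS factor gene, and Hr4, an ecdysone-induced nuclear receptor gene. Per 10 kb this was 3.57 regions for Eip74EF, 3.50 for sbb, 3.28 for Hr4, 2.44 for Eip75B and 0.683 for kirre.

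Of 13945 protein-coding genes, 2993 (21.5%) were bound, and 1647 of these were also bound in each replicate's own list. Among the 22 gene lists, 7 had more bound members than other genes and 1 had fewer (Fisher's exact test, Benjamini-Hochberg adjusted). Against random lists matched on the number of TSSs, 5 lists differed, 4 of them among these 8. Against lists matched on head-to-head arrangement as well (an opposite TSS of another gene within 500 bp upstream), 7 differed, 6 of them among the 8. Genes with many TSSs have more chances of a promoter peak. The matching on TSS number put genes with 5 or more TSSs into 1 class, so differences within that class were not matched.

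Ecdysone response genes, which respond to the steroid that times metamorphosis, were bound in 16 of 26 cases (61.5%, against 21.4% of other genes, odds ratio 5.88, adjusted exact p = 8.18e-05). Signals were 832.4 at E23, 485.7 at Eip75B, 347.5 at tai and 325.6 at Eip93F. In the ecdysteroid synthesis list 1 of 13 genes was bound, Cyp18a1, whose product inactivates ecdysteroids, with a signal of 76.5, and this list did not pass the test (adjusted exact p = 0.444). BTB-domain transcription factor genes were bound in 11 of 15 cases (odds ratio 10.1, adjusted exact p = 0.000138), among them Trl (389.7), lola (370.8), psq (348.2) and lolal (317.5). With lists matched on the number of TSSs both calls were lost, at adjusted permutation p = 0.061 for ecdysone response and 0.111 for BTB-domain genes, with 1.58 and 1.52 times the bound members of matched lists. With head-to-head arrangement matched too, ecdysone response genes passed (ratio 1.68, adjusted permutation p = 0.0213) and BTB-domain genes did not (ratio 1.58, adjusted permutation p = 0.0733).

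In the Wnt, Hedgehog, Dpp and EGFR list 16 of 29 genes were bound (odds ratio 4.52, adjusted exact p = 0.000268), including the kinase gene sgg (605.1), nkd (335.7), the EGFR ligand gene spi (328.2) and the EGFR antagonist gene aos (237.3). In the Notch pathway 12 of 23 were bound (odds ratio 4.0, adjusted exact p = 0.00362), led by the corepressor gene gro (679.0), numb (479.1), neur (227.5) and mam (211.4). Both lists also passed with lists matched on TSS number (adjusted permutation p = 0.0158 and 0.0088), in which genes with 5 or more TSSs were not told apart. The Notch call was lost with replicate 2's peaks alone (odds ratio 2.5, adjusted exact p = 0.0964) and at a global IDR limit of 0.001 (odds ratio 2.97, adjusted exact p = 0.0599). Of the circadian clock genes 7 of 12 were bound (odds ratio 5.13, adjusted exact p = 0.0162), including sgg, cry (224.2), vri (170.9) and per (129.3), and the call was lost with matched lists (ratio 1.82, adjusted permutation p = 0.169). The clock call was also lost with head-to-head arrangement matched too (ratio 2.02, adjusted permutation p = 0.0733) and at the limit of 0.001 (odds ratio 3.39, adjusted exact p = 0.115).

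Cytoplasmic ribosomal protein genes had 42 of 92 members bound (45.7%, odds ratio 3.10, adjusted exact p = 2.8e-06), with signals of 448.6 at RpL34b, 300.1 at RpL32, 256.0 at RpL41 and 232.2 at RpL14. In highly expressed housekeeping genes 13 of 20 were bound (odds ratio 6.82, adjusted exact p = 0.000146), with signals of 1369 at Gapdh2 and 599.0 at Eno, both glycolytic enzyme genes. The housekeeping call was lost with either replicate's peaks alone (adjusted exact p = 0.103 for replicate 2 and 0.289 for replicate 1), at the limit of 0.001 (0.0775) and with lists matched on TSS number (ratio 1.71, adjusted permutation p = 0.0557). It passed with head-to-head arrangement matched too (ratio 1.69, adjusted permutation p = 0.0453). Ribosomal protein genes passed with both matchings (ratios 1.75 and 1.66, adjusted permutation p = 0.0022 and 0.00147), and their call was lost with replicate 1's peaks alone (odds ratio 1.62, adjusted exact p = 0.171).

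Chemosensory receptor genes stood at the other end, with 2 of 179 bound (1.12%, odds ratio 0.0407, adjusted exact p = 6.89e-15), namely Ir67c (92.8) and Ir60e (82.9). Gr10a and Gr10b, gustatory receptor genes, were among the members with no summit in the list analysed. The neuronal function list had 2 of 23 bound, elav (731.9), which encodes a neuronal RNA-binding protein, and the potassium channel gene Sh (362.8). It missed the threshold against other genes (adjusted exact p = 0.316) and passed it, with fewer bound members, against lists matched on TSS number (ratio 0.235, adjusted permutation p = 0.0154). Spermatogenesis genes had 1 of 22 bound, nanos (149.9), at an adjusted exact p of 0.131.

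The remaining lists did not pass the test against other genes. In the heat shock list 8 of 19 were bound (adjusted exact p = 0.109), including the small heat shock protein genes Hsp27 (1340) and Hsp26 (472.5), and with a promoter window of 1000 bp the adjusted exact p was 0.0382. In the Polycomb and trithorax group 10 of 29 were bound (adjusted exact p = 0.185), among them ph-p (1563), brm (924.9) and E(z) (337.8), and the list passed with replicate 1's peaks alone (adjusted exact p = 0.0296) and at the limit of 0.001 (odds ratio 3.06, adjusted exact p = 0.0311). Bound members numbered 10 of 26 for the cell cycle, with Dp at 685.8 (adjusted exact p = 0.113), and 7 of 18 for cell death and autophagy, with hid at 403.9 and Atg7 at 386.6 (adjusted exact p = 0.154). They numbered 6 of 19 for insulator proteins, with Chro at 1472 and Cp190 at 540.2 (adjusted exact p = 0.396), and 6 of 22 for the immune response, with cact at 311.2 (adjusted exact p = 0.547). Neural fate regulators had 5 of 22 bound, with da at 135.2 (adjusted exact p = 0.858), and Hox and homeodomain patterning genes had 4 of 22, with Dll at 1829 and pb at 127.9 (adjusted exact p = 1). Of the tissue lists, muscle had 5 of 28 bound, with sls at 512.5 and Mef2 at 204.2 (adjusted exact p = 0.858), photoreceptor had 3 of 22, with oc at 168.0 (adjusted exact p = 0.697), and cuticle and pigment had 4 of 31, with b at 102.1 and ple at 77.8 (adjusted exact p = 0.49).

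**Figure D3:**
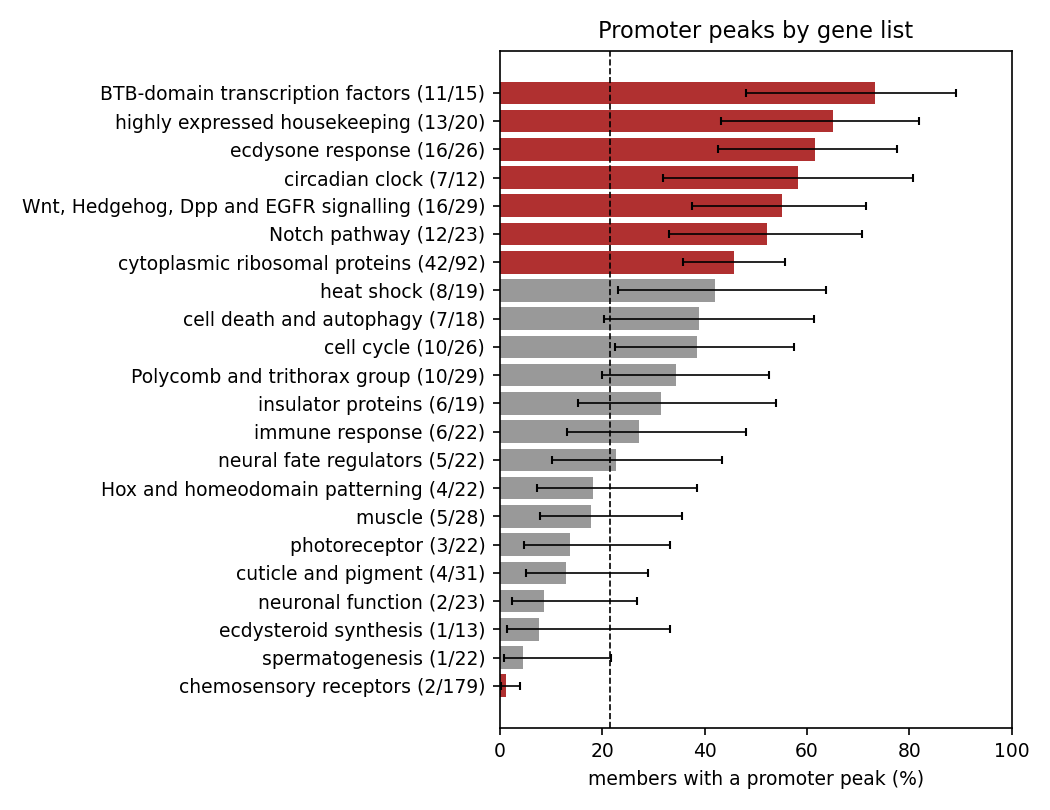
Share of members with a promoter peak in percent (x axis) for each of the 22 gene lists, with bound and total members in brackets and Wilson 95% intervals as error bars. Red bars passed the adjusted test, and the dashed line marks the 21.5% of all protein-coding genes that were bound.

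Sequences at the summits were compared with each peak's own flank. Of the 22 motifs, 9 differed (exact binomial test, Benjamini-Hochberg adjusted), 5 of them more frequent at summits. The TATA box sequence TATAAA occurred at 17.7% of summits and in 12.6% of flanks (adjusted exact p = 3.75e-16), the GATA site AGATAA at 6.85% and 5.6% (adjusted exact p = 0.00436) and the GAGA element GAGAGAG at 3.27% and 2.41% (adjusted exact p = 0.00436). The motif 1 core GGTCACAC was present at 42 summits and in 16 flanks (adjusted exact p = 0.00316), and the DNA replication-related element TATCGATA at 49 and 23 (adjusted exact p = 0.00719). Less frequent at summits were the Pleiohomeotic core GCCAT (13.9% against 17.9%, adjusted exact p = 7.47e-11), the E-box CAGCTG, the nuclear receptor site AGGTCA and the Zelda site CAGGTA. At promoter summits alone, the GAGA element occurred at 4.49% against 1.66% (adjusted exact p = 3.33e-09) and TATCGATA at 45 summits against 10 flanks (adjusted exact p = 1.51e-05). Among distal summits the GAGA element occurred at 2.53% against 2.24% (adjusted exact p = 0.627), and TATCGATA at 4 summits against 11 flanks (adjusted exact p = 0.326). The motif 1 core call was lost there, at 14 summits against 8 flanks (adjusted exact p = 0.525), in the same direction as over all peaks. Ratios were also taken of summits to flanks with the sequence in only that window, with a small constant added to both counts. Over all peaks they were 1.38 for the GAGA element, 2.11 for TATCGATA and 2.58 for the motif 1 core. With replicate 1's fewer peaks alone they were 1.23, 1.87 and 1.67, in the same direction, and the calls were lost (adjusted exact p = 0.24, 0.234 and 0.341). The calls were also lost at the limit of 0.001, with ratios of 1.19, 1.72 and 1.53 (adjusted exact p = 0.396, 0.298 and 0.576). The GATA site, with a ratio of 1.24 over all peaks, was at 1.11 with replicate 1's peaks alone, 1.09 with 100 bp windows and 1.06 at promoter peaks alone, and its call was lost in each (adjusted exact p = 0.31, 0.174 and 0.749). CAGCTG, at 0.732 over all peaks, was at 0.772, 0.904 and 0.943 in these settings, and its call was lost in each (adjusted exact p = 0.0843, 0.174 and 0.749). The Zelda site, at 0.642 over all peaks, lost its call with replicate 1's peaks alone (0.706, adjusted exact p = 0.112) and at distal peaks (0.776, adjusted exact p = 0.338). The nuclear receptor site, at 0.646, lost it at distal peaks (0.809, adjusted exact p = 0.33). Of 2080 6-mers, 898 differed, 296 of them more frequent at summits and led by AAAATA (32.0% against 21.1%), and 602 less frequent.

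Base composition differed between summits and flanks. The mean GC content was 37.9% within 50 bp of summits and 41.6% in flanks, a difference of -3.76 percentage points (95% interval half-width 0.367). It was -11.0 points in the strongest of 5 equal groups of peaks by signal, whose summits had 31.5% GC, and 2.13 points in the weakest group, with 43.0% GC. With flank windows matched on GC content, the TATA box and GATA site calls were lost (adjusted exact p = 0.975 for both), as were those of the Zelda site (0.436), the E-box CAGCTG (0.572) and the nuclear receptor site (0.221). The CA repeat CACACAC was more frequent at summits than in these windows (4.78% against 3.79%, adjusted exact p = 0.0153). Of the 6-mers 247 differed from these windows, 117 of them more frequent at summits and led by ACAGTG (6.20% against 3.17%), and 130 less frequent. AAAATA stood at 32.0% against 29.4% (adjusted exact p = 0.00268). The Pleiohomeotic core (adjusted exact p = 9.94e-05), the GAGA element (3.27% against 1.63%), motif 1 core (42 against 14) and TATCGATA (49 against 26) still passed, the last 3 at an adjusted exact p of 9.13e-10, 0.00172 and 0.0466. These windows were matched on GC content and not on distance to a TSS. The last 3 calls therefore cannot be set apart from the position of many summits at promoters, and none of the 3 was called at distal summits against plain flanks.

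**Figure D4:**
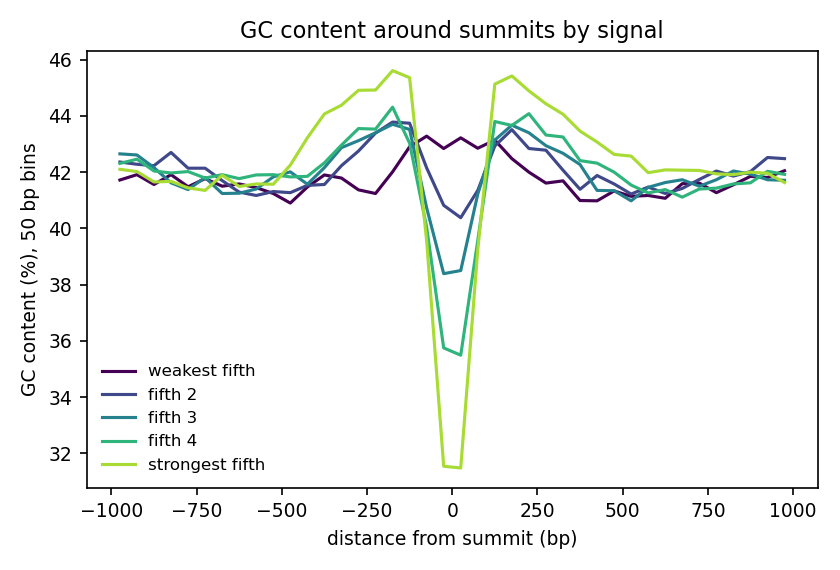
Mean GC content in percent in bins of 50 bp (y axis) by distance from the summit in bp (x axis), for peaks split into 5 equal groups by signal, 1 line each. The dip at the summit is deepest in the strongest group, where the window within 50 bp of summits had 31.5% GC.

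Peaks were unevenly spread over the chromosome arms. Chromosome 4, a small and largely heterochromatic chromosome, held 11 peaks, 0.142 times the number given by its share of length (exact binomial test, adjusted exact p = 4e-20). Arm 3L held 1767 peaks (ratio 1.10, adjusted exact p = 5.06e-05), X held 1450 (1.07, adjusted exact p = 0.00427) and 3R held 1717 (0.933, adjusted exact p = 0.0021), and 2L and 2R did not pass the test (ratios 0.975 and 0.977, adjusted exact p = 0.33 for both). On chromosome 4, 3.43% of candidate and thresholded peaks together had passed the threshold, against 8.46% on the other arms (Fisher's exact test, odds ratio 0.384, p = 0.000556). By the share of TSSs in place of length, 2L and 2R held fewer peaks (ratios 0.911 and 0.896, adjusted exact p = 0.000186 and 5.18e-06). The X call was lost with replicate 2's peaks alone (ratio 1.05, adjusted exact p = 0.0972).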

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

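The ranked list with a signal for each replicate held 175 peaks within the IDR limit that were not among the conservative peaks, and these were picked out because they carry signal outside the main measurement. They were not analysed here. Such a surplus was not particular to this list. Within the limit, replicate 1's ranked list held 4590 peaks against 4471 in its thresholded list, and replicate 2's held 7200 against 7044. For the other lists of the series the numbers were 8647 and 8452. The cause was not tested.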

How the results depend on the processing

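The limit of 0.001, the collapsing of overlapping peaks, the GC-matched windows and the lists matched on head-to-head arrangement besides TSS number were chosen after the data were seen. The planned limit of 0.01 removed no peak and so tests nothing. The promoter share, the share of replicate 1 peaks found in replicate 2 and the count of arms kept their side of the threshold or stayed within 1.5 times under each alternative run. Leaving out a replicate gave 4471 to 7044 peaks, 1823 to 2858 bound genes and 4 to 11 motifs, and the limit of 0.001 gave 4181 peaks and 1794 bound genes. The replicate correlation was 0.46 over all ranked peaks, 0.78 at the limit of 0.001 and 0.78 with overlapping peaks collapsed. Matching on TSS number gave 5 differing lists, 4 of them called in the main test. Distal peaks, farther than 500 bp from any TSS, gave 4 motifs, all 4 called in the main test, and GC-matched windows gave 5, with 4 of them called in the main test.

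Single lists, motifs and arms changed direction in 14, 28 and 1 cases, most of them past no threshold on either side. Over the other cases, list values kept direction and side of the threshold in 188, lost the call in 13 and gained it in 5. For motifs these counts were 160, 20 and 12, and for arms 38, 1 and 2. The counts of 188, 160 and 38 included the planned limit on the global IDR, which removed no peak. Every case under that limit was unchanged by construction and is no sign of stability. Called in the main test and reversed were the DNA replication-related element, at 0.391 among distal peaks, and the TATA box and GATA site, at 0.985 and 0.987 with GC-matched windows, all as ratios of summits to flanks with the sequence in only that window. All motif ratios in this section have the same small constant added to both counts. The CA repeat, not called in the main test, reversed at the limit of 0.001 to 0.755 (adjusted exact p = 0.0241).

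The remaining reversals passed no test. As odds ratios of lists, Hox and homeodomain patterning stood at 1.57 with the other thresholded list, 1.07 at the limit of 0.001 and 1.04 with a 250 bp promoter window. Neural fate regulators stood at 0.745 with the other thresholded list, 0.322 at the limit of 0.001 and 0.861 with a 1000 bp window, and muscle at 1.13 at the limit of 0.001. Leaving out a replicate gave 0.665 to 2.69 for Hox and homeodomain patterning, 0.612 to 0.665 for neural fate regulators, 0.798 to 1.55 for muscle, 0.316 to 1.14 for photoreceptor, 0.867 to 1.73 for the cell cycle and 0.862 to 1.48 for the immune response. For motifs it gave 0.854 to 1 for the CA repeat, 1.10 to 1.25 for the TCF site and 0.478 to 1.70 for the CTCF core, and for the peak ratio of arm 2L 0.996 to 1.01.

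Motif ratios with GC-matched windows were 1.04 for the AP-1 site, 0.986 for the BEAF-32 core and 0.884 for the homeodomain core. The homeodomain core, uncalled in the main test, was called more frequent with replicate 1's peaks alone (1.42, adjusted exact p = 0.00012) and at the limit of 0.001 (1.37, 0.000803). The BEAF-32 core was called more frequent with replicate 2's peaks alone (1.23, adjusted exact p = 0.0496) and at promoter peaks (1.38, 0.0499). The Su(H) site was called less frequent with replicate 2's peaks alone (0.579, adjusted exact p = 0.00633), the other thresholded list (0.0412) and 100 bp windows (0.0458). The su(Hw) core was called more frequent with the other thresholded list (adjusted exact p = 0.0412), at the limit of 0.001 (0.0353) and with peaks collapsed (0.0173). The E-box CACGTG was called less frequent with peaks collapsed (0.661, adjusted exact p = 0.0361). At the limit of 0.001 the motif ratios were 0.368 for Grainyhead, 1.15 for the TCF site and 1.03 for the initiator. Distal peaks gave 0.912 for the BEAF-32 core, 1.47 for the CTCF core and 0.946 for the CA repeat, and promoter peaks gave 0.918 for the CA repeat, 1.11 for the E-box CACGTG and 1.10 for the initiator. With overlapping peaks collapsed the CA repeat was at 0.891, Grainyhead at 0.905 and the initiator at 1.01. The other thresholded list gave 1.03 for the AP-1 site, 1.34 for the CTCF core and 0.852 for Grainyhead, and 100 bp windows gave 0.695 for Grainyhead and 0.975 for the homeodomain core. The cause was not tested, except that the stricter limit and single replicates hold fewer peaks and the matched windows remove the base composition. Depth is unknown, so the difference in peak number between the replicates cannot be set against it.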

Other observations

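The tests for head-to-head genes, first introns, tRNA genes and GC content were set up after the peaks were seen. Those of mitochondrial ribosomal protein genes, of ecdysone gene regions and of distal peaks with GAGAGAG were set up after the result itself was in view. Genes with an opposite TSS of another gene within 500 bp upstream, called head-to-head here, were bound in 1304 of 3815 cases (34.2%), against 1689 of 10130 other genes (16.7%, Fisher's exact test, odds ratio 2.59, p = 8.84e-105). Among genes with 1 TSS the shares were 28.4% and 10.7% (odds ratio 3.31). A summit near such a pair of TSSs can count for both genes, and each window holds a further promoter. Part of the excess therefore follows from the definition. Genes of a pair are not independent, which the exact p does not allow for. Intronic summits lay in a first intron in 2223 of 3416 cases (65.1%), against 42.2% of intronic bases (exact binomial p = 4.63e-159). The 26 ecdysone response genes held 176 peak regions in their bodies or 1 kb upstream, against a mean of 61.7 in draws of genes of like length (ratio 2.85, permutation p = 0.0002, the smallest that 10000 draws can give). Of these regions 90 lay in Eip75B, Eip74EF, Hr4 and tai, whose high counts had prompted the test. With the 12 genes of most regions left out of the list and of the draws, the remaining 22 genes held 86 regions against a mean of 39.8 (ratio 2.16, permutation p = 0.0006). Both sets of draws were matched on gene length and not on the number of TSSs, so an excess apart from TSS number was not tested for regions.

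Mitochondrial ribosomal protein genes were bound in 25 of 73 cases (34.2%), against 21.4% of other genes (Fisher's exact test, odds ratio 1.91, p = 0.0141). Among head-to-head genes alone 23 of 53 of them were bound, against 34.1% of the rest (odds ratio 1.49, exact p = 0.189). The group was prompted by mRpL41 and mRpS10 among the 25 strongest peaks. With the genes of those peaks left out throughout, 23 of 71 were bound against 21.3% (odds ratio 1.77, exact p = 0.0289), and among head-to-head genes 22 of 52 against 34.0% (odds ratio 1.43, exact p = 0.238), so the excess was not shown apart from that arrangement.

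Of the 328 main peaks with a signal under 20, 327 overlapped a stronger main peak, and 8 intervals were listed more than once. At the peak in CG32121 the ratio of replicate 2 over replicate 1 signal was 0.86, and 82 of 7322 peaks (1.12%) had a ratio as low. This peak was chosen for that ratio after its values were seen.

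Summits were poorer in GC than their flanks, most of all at the strongest peaks, with a Spearman rho of -0.361 across peaks between signal and summit GC. Candidate peaks that missed the threshold differed in the opposite direction, by 3.56 percentage points (half-width 0.0946), which argues against AT-rich summits in every call. Peaks with no exon within 550 bp differed by -3.85 points (half-width 0.505), which argues against neighbouring exons. The ratio of replicate signals was nearly unrelated to summit GC (rho of -0.0743 across peaks). These peaks had passed a limit that asks for agreement between the replicates, so this cannot decide on a bias in 1 library alone. In the replicates' own lists the difference was -5.67 points for replicate 1 (half-width 0.475) and -4.24 points for replicate 2 (half-width 0.383). A GC bias shared by both libraries also stays open, because no input was analysed here, and no biological explanation was tested.

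Ribosomal protein promoters were bound more often than genes matched on head-to-head arrangement and number of TSSs (42 against a mean of 25.3, permutation p = 0.0002, the smallest the draws can give), which argues against those features as the whole cause. Signal at any strongly transcribed locus cannot be told apart from binding. Of 290 tRNA genes 39 (13.4%) had a summit within 500 bp, which is above the 5.19% of random positions (exact binomial p = 6.53e-08). It is below the 45.7% of ribosomal protein genes and the 21.5% of all protein-coding genes. Among protein-coding genes with 1 TSS, 28.4% of head-to-head genes and 10.7% of the others were bound. An excess of tRNA genes over other genes was therefore not shown. Neighbouring tRNA genes can share a summit, which the binomial test does not allow for. No untagged sample was analysed here, which keeps this open, and no biological explanation was tested.

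GAGAGAG occurred at 3.91% of summits in the weakest of 5 equal groups of peaks by signal and 1.11% in the strongest (Fisher's exact test, odds ratio 3.63, p = 6.56e-07). The difference held among distal peaks (exact p = 1.95e-06), which argues against a different mix of promoter and distal peaks. With peaks compared within bins of summit GC the odds ratio was 0.954 (permutation p = 0.957), so the base composition of the summits may account for the difference. No biological explanation was tested. The 6-mer CAGTGC was picked from a scan of 2080 6-mers against GC-matched windows, in which it occurred at 6.55% of summits and in 3.87% of windows (adjusted exact p = 5.5e-11).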
